A study of Homo sapiens with 9 samples.

How the data were processed

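Transcript levels were measured by mRNA sequencing in HaCaT cells, an immortalised line of human epidermal keratinocytes. The labels place 9 libraries in 3 groups of 3. These are control cells, cells laden with melanosomes (the pigment organelles that melanocytes pass to keratinocytes), and melanosome-laden cells treated with glabridin, an isoflavan from licorice root. Dose, exposure time and the origin of the melanosomes are not given in the sources used here. Per the labels' protocols, poly(A) RNA was made into strand-specific libraries with dUTP and sequenced as read pairs on an Illumina platform. Groups and replicate numbers were taken from the sample titles and treatment labels.

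The authors deposited whole-number counts per gene, not normalized, for every library, which per the file headers stand beside TPM for the same genes. A second deposited table of TPM values held the same numbers, with a largest difference of 0. Reads were placed on hg38, per the submitters' processing notes. The aligner, the counting program, its treatment of strand and the gene annotation are not given in the sources used here. Of 20263 Ensembl identifiers, 20148 matched a symbol in the reference name table, and 20224 had coordinates in GENCODE release 29 on GRCh38, which was used for the positions printed here. Deposited counts summed to between 39653425 and 46690787 per library. Among counts from 1 to 49, between 69.9% and 72.2% were even, against 48.7% to 51.1% of counts over 500. In each library counts of 2 outnumbered counts of 1. Counting both reads of a pair would leave such a pattern, but whether this was done is not given. If it was, intervals computed from the counts are too narrow and floors too low. In any case they cover counting error only, and leave out PCR duplication.

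Replicates were first compared with each other. The chi-square per gene between replicate pairs ran from 3.23 to 5.42 in control, from 4.46 to 14.7 in the melanosome group and from 32.4 to 109.8 in the glabridin group, so each pair differed by more than sampling noise and all 9 libraries were kept as separate samples. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. In a principal component analysis of log2 CPM, the first component held 83.1% of the variance and parted control from the other groups. The second held 9.81% and parted glabridin from melanosome libraries. The third held 2.56% and parted replicates 2 and 3 of the glabridin group.

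Before the data were examined, the tests, the gene lists and the alternatives were fixed. Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM factors, filterByExpr by group), with all 9 libraries in a single fit and no replicate block. Of the genes, 13912 passed the filter. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 were called. Standard errors of log2 fold changes were derived from the F statistic. Levels are CPM on TMM-scaled library sizes, given as mean ± SD of 3 libraries. Where all control libraries held 0 counts, a fold is given as a lower bound against 3 counts over the group, equal to 0.0234 CPM. Where the control group held 1 to 3 counts, the ratio is given with its exact (Clopper-Pearson) 95% interval.

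In addition, 28 lists with 774 entries were tested with camera from limma 3.58.1 (preset correlation 0.01), and p-values were adjusted over the lists within each comparison. Of the entries, 2 were not found (SOD2 and H3C2). Camera compares a list with all other genes, so it is little affected by scaling, whereas counts of members are. Genes are named by a rule fixed in advance. For each of the first 2 comparisons it takes the 5 largest rises and 5 largest falls among called genes with non-overlapping libraries and a mean log2 CPM of at least 1, a separation that chance alone gives in 10% of genes. It adds the 2 called members with the smallest p from the 8 lists with the smallest camera p, and SQSTM1, MAP1LC3B, LAMP1, TFEB and PMEL. The rule took 31 and 28 genes, of which one is not reported here, though it stays in the counts of genes and lists. Other members of lists are given as examples chosen after their values were seen.

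The edgeR script was tested on simulated counts with 13750 genes passing the filter. For melanosome vs control, 52.2% of genes changed 1.5-fold, 92.5% of genes changed 2-fold and 97.0% of genes changed 4-fold were recovered with the right sign. For glabridin vs melanosome, these shares were 44.8%, 92.5% and 92.4%. Of 173 and 161 calls, 12 and 8 were among unchanged genes. In each comparison only 67, 67 and 66 genes were changed at these folds, with the same spread in every group. The shares need not hold in the real data, where far more genes were called and the glabridin replicates differed more.

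Alternatives were RLE, upper-quartile or no scaling factors, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) or log2(TPM + 0.1) for genes with a mean TPM of at least 1 in a group, no count filter or a CPM of at least 1 in 3 libraries, a fit of the 2 groups alone, a replicate block, each library left out, a test against a fold of 1.2, and mitochondrially encoded genes left out. Chosen after seeing the data were library totals without factors, halved counts, and leaving out genes with at most 3 counts in every control library and a mean of at least 1 CPM in both melanosome-laden groups. The same holds for leaving out single libraries in the tests of lists outside autophagy, lysosome and nuclear-encoded oxidative phosphorylation. FPKM, also deposited by the authors, was not used here. For the closing section, the trend of each library with GC content or transcript length was removed by loess. The covariance of the first 2 comparisons was taken over all 6 ways of giving them different melanosome libraries. Reads of near-identical genes, such as HSPA1A and HSPA1B, the AKR1C genes, keratins and genes with many pseudogenes, cannot be told apart with certainty.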

Results

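Expression was profiled in 9 libraries of HaCaT keratinocytes, with 3 control, 3 melanosome-laden and 3 melanosome-laden, glabridin-treated libraries. Per the series design, the groups were sequenced to study how glabridin promotes the degradation of melanosomes in keratinocytes. Deposited counts per library totalled 41793696 to 45839573 in control, 39653425 to 46690787 in the melanosome group and 42582054 to 46591852 in the glabridin group. All fold changes below come from TMM-scaled counts tested with edgeR.

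The comparison of melanosome-laden with control cells asks how carrying melanosomes changes keratinocyte transcription. Transcripts of pigment cells separated the groups. PMEL, which encodes the fibrillar protein of the melanosome (chromosome 12, 55954105 to 55973317, GRCh38), averaged 3.20 ± 0.315 CPM (SD, n = 3) in control and 2109 ± 65.8 CPM in melanosome libraries. The largest rises among genes open to naming were those of TRPM1 (chromosome 15, 31001061 to 31161273), A2M, PDK4, TYR (chromosome 11, 89177452 to 89295759) and RUNX3, which had 0 counts in every control library. Against the floor of 3 counts over the control group, TRPM1 was at least 7943-fold higher, A2M at least 5362-fold, PDK4 at least 5105-fold, TYR, the gene of the key enzyme of melanin synthesis, at least 3888-fold, and RUNX3 at least 3441-fold. These bounds take each count as a separate fragment, and would be lower if both reads of a pair were counted. SOX10, a transcription factor of the neural crest lineage, had 2 control counts, both in replicate 2, and a ratio of 7480 (95% counting interval 2070 to 61770.5). Of 22 tested melanocyte markers, 21 rose and 1, APOD, fell, and the same numbers passed when adjusted over the list alone (camera, adjusted p = 1.8e-51, and adjusted p = 0.0235 with an estimated correlation). Their summed level was 216 ± 6.38 CPM in control, 3662 ± 67.4 CPM in melanosome and 2957 ± 936 CPM in glabridin libraries. In total, 234 genes had at most 3 counts in each control library and at least 1 CPM in both melanosome-laden groups. They held 0.343% ± 0.00479 of melanosome counts and 0.306% ± 0.0689 of glabridin counts. These shares leave out PMEL and every other gene with more than 3 counts in a control library. They therefore do not measure all RNA that pigment cells could have added, which may be more. Counts do not show which cell a transcript came from, and whether pigment cells were in the culture was not tested, so the values of this comparison describe whole libraries and need not be those of keratinocytes alone.

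Genes of cell division rose together with these transcripts. Of 40 tested cell cycle and DNA replication genes, 36 rose and 1 fell, with the same numbers adjusted over the list alone (camera, adjusted p = 3.91e-21, and adjusted p = 0.00114 with an estimated correlation). KIF20A, a mitotic kinesin, went from 20.5 ± 1.13 to 103 ± 4.55 CPM (log2 fold change 2.34 ± 0.07 SE). CDC20, an activator of the anaphase-promoting complex, went from 31.5 ± 0.393 to 147 ± 9.05 CPM (2.22 ± 0.07 SE). Of 30 interferon-stimulated genes, 18 rose and 3 fell, as also adjusted over the list alone (camera, adjusted p = 4.36e-06, and adjusted p = 0.0197 with an estimated correlation). IFI6 was 18.7-fold and IFI27 21.5-fold higher, with log2 changes of 4.22 ± 0.09 and 4.42 ± 0.11 SE. No member of either list was among the 234 genes lacking in control, but both lists rose in the libraries where the melanocyte markers rose.

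Several stress and metabolic lists shifted with less certainty, because none of their calls held with an estimated correlation. Among 28 ATF4 targets of the integrated stress response, 20 rose and 1 fell (20 and 2 adjusted over the list alone; camera, adjusted p = 1.16e-05, against adjusted p = 0.279 with an estimated correlation). GDF15, a stress-induced cytokine gene, was at 0.540 ± 0.0891 CPM in control and 143 CPM with melanosomes (log2 change 8.04 ± 0.20 SE), and ASNS, the asparagine synthetase gene, from 5.40 ± 0.579 to 57.7 ± 2.15 CPM. Of 26 NRF2 antioxidant targets, 19 rose and 2 fell, also adjusted over the list alone (camera, adjusted p = 0.0098, against adjusted p = 0.213 with an estimated correlation). HMOX1, which encodes haem oxygenase, was 18.8-fold higher. AKR1C1 was 1.99-fold higher, a value made uncertain by reads shared with its near-identical paralogs. Of 28 glycolysis and hypoxia genes, 18 rose and 2 fell (20 and 2 adjusted over the list alone; camera, adjusted p = 0.00281, against adjusted p = 0.408 with an estimated correlation), among them the glucose transporter gene SLC2A3 (log2 change 6.35 ± 0.18 SE) and the hexokinase gene HK2 (1.34 ± 0.06 SE). Of 21 matrix and TGF-beta genes, 12 rose and 4 fell, also adjusted over the list alone (camera, adjusted p = 1.71e-05, against adjusted p = 0.246 with an estimated correlation). VIM, an intermediate filament gene also active in pigment cells, went from 0.182 ± 0.0908 to 641 ± 19.1 CPM, and SERPINE2, a secreted protease inhibitor gene, was 35.1-fold higher. Among 20 genes of fatty acid synthesis and lipid droplets, 10 rose and 2 fell, also adjusted over the list alone (camera, adjusted p = 0.0228, against adjusted p = 0.279 with an estimated correlation). This list contains PDK4, which control lacked, and without the 234 such genes its adjusted p by camera was 0.106. The melanocyte markers rose in the same libraries as each of these lists.

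Genes of translation and of keratinocyte differentiation fell. Of 40 cytosolic ribosomal protein genes, 39 fell and none rose, also adjusted over the list alone (camera, adjusted p = 2.11e-11, against adjusted p = 0.408 with an estimated correlation). RPS6 dropped from 2311 ± 42.0 to 1044 ± 25.5 CPM and RPL6 from 1265 ± 21.6 to 669 ± 14.2 CPM, with the caution that processed pseudogenes can share their reads. Of 40 keratinocyte differentiation genes, 21 fell and 7 rose, also adjusted over the list alone (camera, adjusted p = 0.0098, against adjusted p = 0.246 with an estimated correlation), and IVL, which encodes the cornified envelope protein involucrin, went from 114 ± 3.06 to 33.8 ± 2.18 CPM. The largest falls among genes open to naming were those of DMBT1, a mucosal scavenger receptor gene (log2 change -3.43 ± 0.17 SE), CYP1B1, a target of the aryl hydrocarbon receptor (-2.68 ± 0.22 SE), AKAP9 and TRIP11, which encode large Golgi proteins (-2.66 ± 0.25 and -2.49 ± 0.28 SE), and DCN, which encodes the proteoglycan decorin (-2.47 ± 0.09 SE). Across all tested genes, which are not independent replicates, the log2 change was related to GC content (Spearman rho 0.295) and to transcript length (rho -0.174). These falls, too, were seen in the libraries where melanocyte markers rose.

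Among the genes most closely tied to the aim of the series, the autophagy core did not differ from other genes as a set. Of 37 core autophagy genes, 7 rose and 12 fell (7 and 11 adjusted over the list alone; camera, adjusted p = 0.884), while fry, which tests the list against no change, gave it as higher (adjusted p = 0.0183). With RLE factors 11 rose and 9 fell, and with library totals alone 15 rose and 6 fell, so the balance turned with the scaling. WIPI1, which binds phosphatidylinositol 3-phosphate at the forming autophagosome, had a log2 change of 2.94 ± 0.10 SE, and RB1CC1, a subunit of the initiating kinase complex, -1.96 ± 0.29 SE. RB1CC1 thus fell at least 2-fold. For such falls as a group, a part played by GC content or transcript length cannot be told apart from a response, as the closing section describes. SQSTM1, an autophagy receptor gene, was at 332 ± 2.46 CPM in control and 338 ± 11.5 CPM in melanosome libraries (log2 change 0.03 ± 0.08 SE, edgeR adjusted p = 0.781). MAP1LC3B, which encodes the LC3B protein of the autophagosome membrane, differed by 0.09 ± 0.07 SE (edgeR adjusted p = 0.305), LAMP1, a lysosomal membrane protein gene, by 0.03 ± 0.07 SE (edgeR adjusted p = 0.673), and TFEB, a regulator of lysosomal genes, by -0.02 ± 0.08 SE (edgeR adjusted p = 0.822). With library totals alone, MAP1LC3B and LAMP1 passed the test, at 0.26 (edgeR adjusted p = 0.0251) and 0.20 (edgeR adjusted p = 0.00736). Of 56 lysosome and acidification genes, 29 rose and 9 fell, also adjusted over the list alone (camera, adjusted p = 0.0316, against adjusted p = 0.628 with an estimated correlation), and CTSL, a lysosomal protease gene, rose from 48.0 ± 0.446 to 166 ± 7.47 CPM. RRAGD of this list was among the 234 genes that control lacked. The changes of autophagy and lysosome genes, with WIPI1 and CTSL, were seen in the libraries where melanocyte markers rose. Which cells their transcripts came from was not tested.

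Nuclear and mitochondrial genes of oxidative phosphorylation were mostly called in different directions, without a test of the difference between the lists. Of 59 nuclear-encoded genes, 38 rose and 5 fell, also adjusted over the list alone, while the list did not pass against other genes (camera, adjusted p = 0.0568). By camera it passed without control replicate 1 (adjusted p = 0.0435), without melanosome replicate 1 (adjusted p = 0.0452) and with a replicate block (adjusted p = 0.0486). It also passed without the 234 genes that control lacked (camera, adjusted p = 0.0179) and with fry (adjusted p = 0.0183). Over its alternatives adjusted p ranged from 0.0179 to 0.815. Of 13 mitochondrially encoded genes, 10 fell and none rose, also adjusted over the list alone (camera, adjusted p = 0.0199, against adjusted p = 0.554 with an estimated correlation). MT-CO1, a subunit of cytochrome c oxidase, had a log2 change of -0.86 ± 0.11 SE. The share of counts from mitochondrially encoded genes was 3.48% ± 0.128 in control and 2.59% ± 0.0754 in melanosome libraries, beside the rise in melanocyte markers.

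In total, 8691 of 13912 genes were called between melanosome and control libraries, of which 4100 rose and 4591 fell (47.2% higher). At least 2-fold changes were seen in 1923 rising and 811 falling genes. Without scaling factors, 5438 genes were higher and 2805 lower (66.0% higher), since library totals moved log2 changes by a median of 0.17, and with limma on log2(TPM + 1) 4971 were higher and 2389 lower (67.5% higher). The balance also turned with RLE factors (53.4% higher), upper-quartile factors (53.9%), DESeq2 (54.2%), only the 2 groups compared (52.5%) and a test against a fold of 1.2 (50.8%), and without mitochondrially encoded genes (54.2%). Small changes in this comparison therefore hold only relative to the TMM scale.

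**Figure D1:**
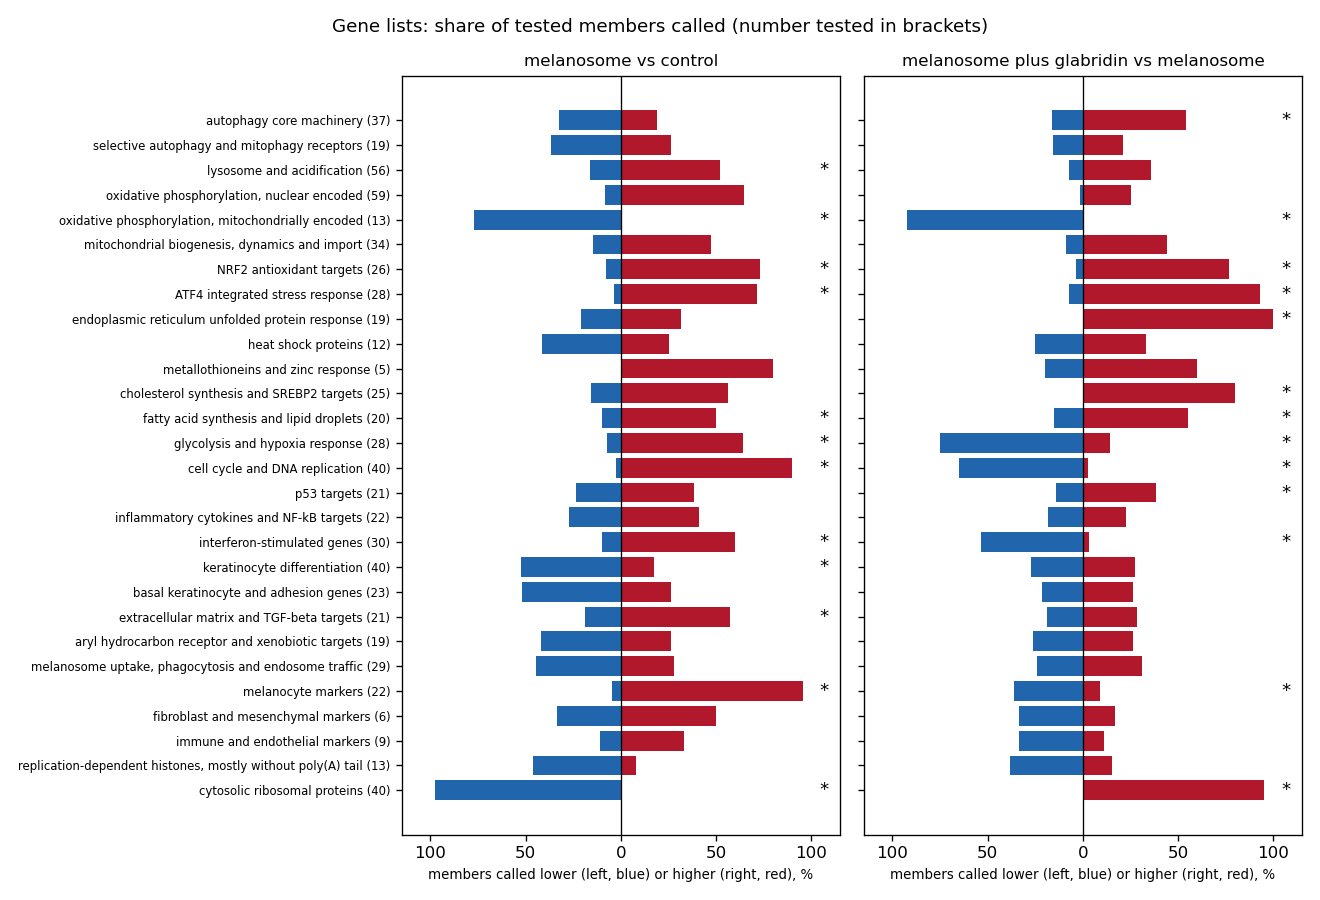
Share of tested members of each of the 28 gene lists called higher (red, right, in percent) or lower (blue, left, in percent) by edgeR in melanosome against control libraries (left panel) and in glabridin against melanosome libraries (right panel). Stars mark lists with a camera adjusted p under 0.05 at the preset correlation. The unfolded protein response list has 19 of 19 members higher under glabridin, and cytosolic ribosomal proteins have 39 of 40 members lower in the left panel and 38 of 40 higher in the right panel.

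The comparison of glabridin-treated with untreated melanosome-laden cells asks what glabridin changes in cells that carry melanosomes. Genes of the endoplasmic reticulum and integrated stress responses rose. HSPA5, which encodes the endoplasmic reticulum chaperone BiP (chromosome 9, 125234853 to 125241330, GRCh38), went from 499 ± 10.1 to 5795 ± 851 CPM (SD, n = 3), an 11.6-fold difference (log2 change 3.54 ± 0.10 SE). HERPUD1, an endoplasmic reticulum degradation gene (chromosome 16, 56932048 to 56944863), went from 67.8 ± 2.62 to 590 ± 81.7 CPM. Of 19 unfolded protein response genes, 19 rose, also adjusted over the list alone (camera, adjusted p = 1.51e-46, and adjusted p = 0.0135 with an estimated correlation). Of 28 ATF4 targets, 26 rose and 2 fell, also adjusted over the list alone (camera, adjusted p = 2.69e-43, and adjusted p = 0.0135 with an estimated correlation). Within it NUPR1, a stress-induced chromatin protein gene, was 24.3-fold higher (4.61 ± 0.24 SE), TRIB3, a pseudokinase gene, 9.27-fold, ATF3 7.86-fold and ATF4 itself 4.05-fold.

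Sterol and antioxidant genes rose as well. Of 25 genes of cholesterol synthesis and SREBP2 regulation, 20 rose and none fell (20 and 1 adjusted over the list alone; camera, adjusted p = 7.09e-20, against adjusted p = 0.0822 with an estimated correlation). INSIG1, a sterol sensor gene, went from 205 ± 5.36 to 1344 ± 112 CPM. Of 20 fatty acid and lipid droplet genes, 11 rose and 3 fell, also adjusted over the list alone (camera, adjusted p = 0.0246, against adjusted p = 0.246 with an estimated correlation, and 0.0807 without the genes that control lacked). Of 26 NRF2 targets, 20 rose and 1 fell (21 and 1 adjusted over the list alone; camera, adjusted p = 6.22e-07, and adjusted p = 0.0135 with an estimated correlation). FTL, the ferritin light chain gene, was 2.66-fold higher and AKR1C1 1.93-fold higher, both with near-identical copies in the genome that could share reads. HMOX1 was at 30.1 ± 1.22 CPM without and 30.7 ± 5.32 CPM with glabridin (edgeR adjusted p = 0.878). Of 21 p53 targets, 8 rose and 3 fell, also adjusted over the list alone (camera, adjusted p = 9.24e-04, and adjusted p = 0.0358 with an estimated correlation), with CDKN1A, a cell cycle inhibitor gene (1.63 ± 0.06 SE), and BBC3, which encodes the pro-apoptotic protein PUMA (1.84 ± 0.09 SE), as examples. Of 40 cytosolic ribosomal protein genes, 38 rose and none fell (39 and none adjusted over the list alone; camera, adjusted p = 1.55e-07, against adjusted p = 0.472 with an estimated correlation). RPL23 changed by 0.40 ± 0.05 and RPL4 by 0.45 ± 0.06 SE, and with library totals alone 28 members rose and 1 fell.

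Genes of glycolysis, division and interferon signalling fell under glabridin. Of 28 glycolysis and hypoxia genes, 21 fell and 4 rose (22 and 4 adjusted over the list alone; camera, adjusted p = 1.07e-10, against adjusted p = 0.0822 with an estimated correlation). EGLN3, an oxygen-sensing prolyl hydroxylase gene, went from 57.2 ± 0.107 to 7.79 ± 0.874 CPM and NDRG1 from 2634 ± 102 to 993 ± 34.4 CPM, while VEGFA, a growth factor gene of the same list, rose by 1.84 ± 0.11 SE. Of 40 cell cycle genes, 26 fell and 1 rose (28 and 1 adjusted over the list alone; camera, adjusted p = 8.09e-07, and adjusted p = 0.0135 with an estimated correlation), with KIF20A at -1.13 ± 0.07 and UHRF1, a DNA methylation maintenance gene, at -1.41 ± 0.13 SE. The member that rose was CDC6, a replication licensing gene (0.85 ± 0.15 SE). Of 30 interferon-stimulated genes, 16 fell and 1 rose, also adjusted over the list alone (camera, adjusted p = 1.15e-05, and adjusted p = 0.0135 with an estimated correlation), with IFI6 at -1.36 ± 0.08 and IFI27 at -1.44 ± 0.10 SE. The largest falls among genes open to naming were those of OLFM4 (-4.28 ± 0.13 SE), GPR15LG (-3.61 ± 0.19 SE), CASP14, a caspase gene of epidermal cornification (-3.50 ± 0.16 SE), APOLD1 (-3.39 ± 0.11 SE) and DMBT1 (-3.14 ± 0.26 SE). With limma on log2(TPM + 1), which shrinks changes of genes at low levels, OLFM4 was at -2.84, CASP14 at -2.42 and DMBT1, with 6 to 14 counts in glabridin libraries, at -0.67. The keratinocyte differentiation list split, with 11 members higher and 11 lower (12 and 13 adjusted over the list alone; camera, adjusted p = 0.0605). It passed without melanosome replicate 1 (adjusted p = 0.0151) or melanosome replicate 2 (adjusted p = 0.0383), over a range of 0.0151 to 0.336 in its alternatives, and with library totals alone 10 members rose and 18 fell. IVL fell by 2.96 on the log2 scale, and KRT10, a suprabasal keratin gene, rose by 1.56 ± 0.08 SE.

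Autophagy genes were moderately higher with glabridin. Of 37 core autophagy genes, 20 rose and 6 fell, also adjusted over the list alone (camera, adjusted p = 0.0275, against adjusted p = 0.0846 with an estimated correlation). With library totals alone, 14 rose and 10 fell. MAP1LC3B went from 123 ± 3.16 to 243 ± 26.7 CPM (log2 change 0.98 ± 0.08 SE, edgeR adjusted p = 3.93e-06), and ATG101, a subunit of the initiating kinase complex, changed by 1.13 ± 0.07 SE. SQSTM1 (chromosome 5, 179806398 to 179838078) went from 338 ± 11.5 to 749 ± 91.7 CPM (1.15 ± 0.08 SE, edgeR adjusted p = 2.19e-06). The list of 19 selective autophagy receptors, which holds SQSTM1, did not pass as a set, with 4 higher and 3 lower (2 and 3 adjusted over the list alone; camera, adjusted p = 0.783), and with library totals alone 1 was higher and 5 lower. BNIP3, a mitophagy receptor gene, fell from 38.8 ± 0.659 to 17.0 ± 4.69 CPM. LAMP1 rose by 0.36 ± 0.07 SE (edgeR adjusted p = 0.00126), and TFEB was at 23.5 and 22.9 CPM (edgeR adjusted p = 0.716). With library totals alone TFEB passed as lower, at -0.22 (edgeR adjusted p = 0.0344). Of 56 lysosome genes, 20 rose and 4 fell, also adjusted over the list alone, and the list did not pass the test (camera, adjusted p = 0.146) but passed without glabridin replicate 3 (adjusted p = 0.0223), over a range of 0.0223 to 0.678 in its camera alternatives. With library totals alone 9 rose and 13 fell.

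Mitochondrially encoded transcripts fell further. Of 13, 12 fell and none rose, also adjusted over the list alone (camera, adjusted p = 1.32e-05, against adjusted p = 0.249 with an estimated correlation). MT-CYB changed by -1.02 ± 0.09 SE and MT-ND1 by -1.25 ± 0.11 SE, and their share of all counts was 1.66% ± 0.180 with glabridin against 2.59% ± 0.0754 without. Of 59 nuclear-encoded oxidative phosphorylation genes, 15 rose and 1 fell (5 and none adjusted over the list alone; camera, adjusted p = 0.202), and with library totals alone 2 rose and 5 fell. Without glabridin replicate 3 the list passed as higher (adjusted p = 0.00841), and without glabridin replicate 2 it pointed lower (adjusted p = 0.935).

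Melanocyte markers changed unequally. Of 22, 8 fell and 2 rose, also adjusted over the list alone (camera, adjusted p = 0.00789, against adjusted p = 0.525 with an estimated correlation). DCT, a melanin synthesis enzyme gene, changed by -2.76 ± 0.15 SE and MITF, the lineage regulator of melanocytes, by -0.92 ± 0.08 SE, while TYR was at 90.9 ± 0.935 and 96.2 ± 24.9 CPM. PMEL averaged 1602 ± 676 CPM with glabridin (log2 change -0.40 ± 0.22 SE, edgeR adjusted p = 0.171) and passed the test without glabridin replicate 2 (-0.79, edgeR adjusted p = 2.42e-05), with library totals alone (-0.58, edgeR adjusted p = 0.0475) and with limma on log2(TPM + 1) (-0.66, limma adjusted p = 0.0196). Without glabridin replicate 3 it was at -0.17 (edgeR adjusted p = 0.373). The marker sum was 2633 CPM in glabridin replicate 1, 4011 CPM in replicate 2 and 2226 CPM in replicate 3, so it differed within the group beside every list above. In all, 6111 genes were called, of which 3301 rose and 2810 fell (54.0% higher), and at least 2-fold changes were seen in 451 rising and 665 falling genes. Without scaling factors 1872 genes were higher and 4573 lower, with limma on log2(TPM + 1) 1786 and 4437 (28.7%), with upper-quartile factors 2332 and 3812 (38.0%), and without mitochondrially encoded genes 2531 and 3518 (41.8%). The balance also turned with RLE factors (46.8% higher) and DESeq2 (46.8%), and without glabridin replicate 1, where 2037 genes were higher and 2884 lower (41.4%). Library totals moved log2 changes by a median of -0.18 and upper-quartile factors by -0.11, so small changes hold relative to the TMM scale.

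**Figure D2:**
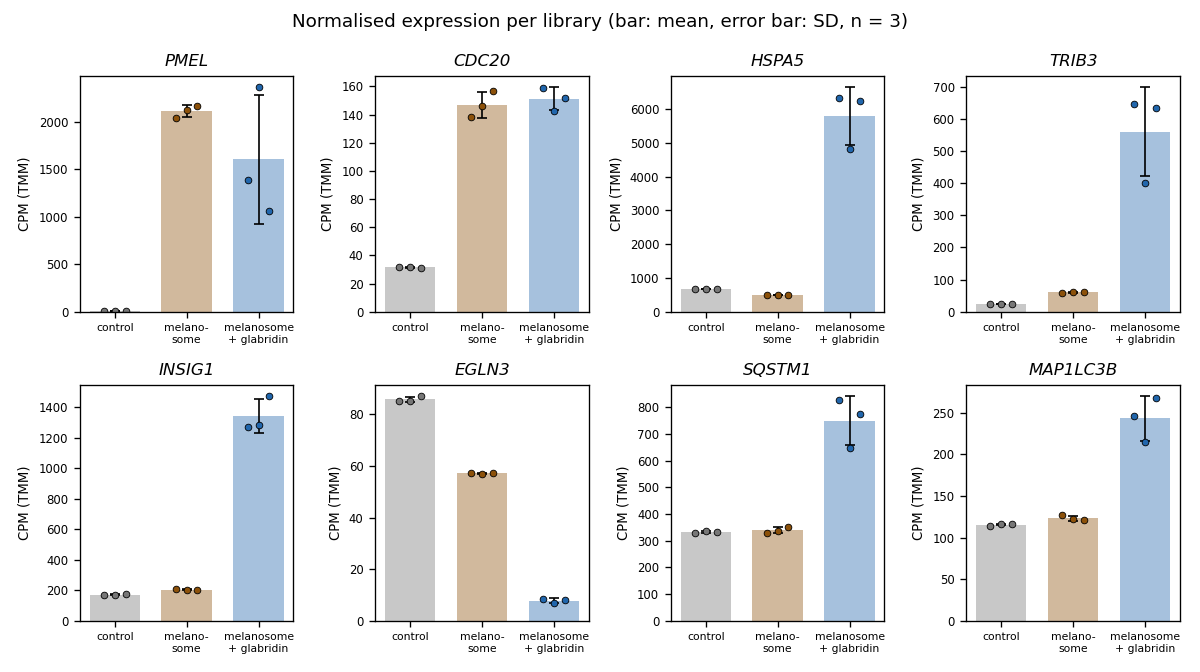
TMM-scaled CPM of 8 genes in the 9 libraries, with points for libraries, bars for group means and error bars for the SD (n = 3), each panel on its own linear axis from 0. HSPA5 lies between 4814 and 6334 CPM in glabridin libraries and at most at 669 CPM in the others, and PMEL ranges from 1063 to 2361 CPM within the glabridin group.

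The comparison of glabridin-treated melanosome-laden cells with control cells asks what differed from untreated cells. It combines the effects of melanosomes and glabridin, and no group received glabridin without melanosomes. A difference here need not have been present with melanosomes alone, where the unfolded protein response list, for example, did not pass (camera, adjusted p = 0.859). In it 9774 genes were called, 5225 higher and 4549 lower. Unfolded protein response genes were higher in 19 of 19 cases (camera, adjusted p = 1.8e-14, against adjusted p = 0.169 with an estimated correlation) and ATF4 targets in 27 of 28, with 1 lower (camera, adjusted p = 2.63e-28, and adjusted p = 0.0307 with an estimated correlation). Cell cycle genes were higher in 29 of 40 cases and lower in 5 (camera, adjusted p = 5.31e-07, and adjusted p = 0.0217 with an estimated correlation). All 13 mitochondrially encoded genes were lower (camera, adjusted p = 5.85e-06, against adjusted p = 0.214 with an estimated correlation). The autophagy core did not pass, with 18 higher and 8 lower (camera, adjusted p = 0.354), although SQSTM1 was higher by 1.17 and MAP1LC3B by 1.07 on the log2 scale. Of 56 lysosome genes, 37 were higher and 8 lower (camera, adjusted p = 0.0069, against adjusted p = 0.452 with an estimated correlation). Interferon-stimulated genes (14 higher, 7 lower; camera, adjusted p = 0.12) and glycolysis and hypoxia genes (10 higher, 12 lower; camera, adjusted p = 0.432) did not pass. Camera compares a list with other genes, so this does not place either list back at control levels. By fry, interferon-stimulated genes were higher than in control (adjusted p = 2.26e-06), and glycolysis and hypoxia genes did not pass (adjusted p = 0.339). IFI6 was still 7.29-fold and IFI27 7.90-fold above control. Melanocyte markers were higher in 21 of 22 cases here too, with 1 lower (camera, adjusted p = 6.87e-31, against adjusted p = 0.072 with an estimated correlation).

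Whether glabridin moved melanosome-associated changes back was examined by setting the first 2 comparisons against each other. Of 13912 genes, 1848 were called in both with opposite signs and 2049 with the same sign. APOLD1, KIF20A, IFI6, IFI27, UHRF1 and HK2 rose with melanosomes and fell with glabridin, whereas DMBT1 and OLFM4 fell in both. Genes that rose and then fell numbered 857, against 828 for independent lists of these sizes, and those that fell and then rose 991 against 1089. For the same sign, 920 genes rose in both against 973, and 1129 fell in both against 927. The comparisons share the melanosome libraries with opposite sign. In 20 simulated data sets with no effect 0 genes were called in both, but without an effect hardly any gene can pass the adjusted threshold. That count therefore cannot show how the shared libraries shift the signs of called genes. The split turned in several settings, at 1033 and 689 with RLE factors, 1077 and 754 with DESeq2, 1231 and 537 with upper-quartile factors, 989 and 961 with limma-voom, 977 and 717 with only the groups compared and 888 and 431 without glabridin replicate 1. It turned narrowly without control replicate 1 (740 and 729), 2 (755 and 750) or 3 (752 and 737). Without glabridin replicate 2 the opposite-sign count was 3097 (1362 and 1735), and without melanosome replicate 3 it was 1221 (584 and 637). Leaving out glabridin replicate 2 also raised the genes called for glabridin vs melanosome from 6111 to 7332. Counts for independent lists and for the same sign are given for the main fit only. Whether opposite signs exceed independent lists was therefore not examined in the alternatives, and may depend on this 1 library. So neither direction held more genes under every alternative. Across genes, which are not independent replicates, the covariance of the log2 changes was -0.091 (correlation -0.10), against -0.018 (correlation -0.49) in the simulations, a difference of -0.073 in covariance. With no melanosome library shared between the comparisons, the covariance averaged -0.077 and ranged from -0.089 to -0.057. Without the 234 genes that control lacked it averaged -0.043. The 3 melanosome libraries are too few to part into sets of at least 2.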

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

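Library totals without factors, halved counts, leaving out the 234 genes that control lacked, and leaving out single libraries for most lists were chosen only after the data were seen. Counts of changed genes stayed within 1.5 times their value under every alternative run, with 1 exception. Against a fold of 1.2, glabridin changed 3414 genes rather than 6111, since that test asks for more than a difference from 0. Leaving out single libraries gave 7499 to 8098 genes for melanosome vs control, 4838 to 7332 for glabridin vs melanosome and 9039 to 10511 for glabridin vs control. With the counts halved, these were 8519, 6112 and 9547 genes. With only the 2 groups compared in the fit, they were 10162, 4970 and 9081 genes. The single fit of all libraries shares its estimate of the spread among groups whose replicates differed unequally, most in the glabridin group. Its standard errors and p-values therefore need not suit each comparison alike. Genes called with opposite signs ranged from 1221 (without melanosome replicate 3) to 3097 (without glabridin replicate 2). The covariance without shared libraries was -0.061 under the stricter filter and -0.043 without the genes that control lacked, against -0.077, and the cause was not tested.

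Of the lists outside autophagy, lysosome and nuclear oxidative phosphorylation, 11 passed for melanosome vs control and 12 for glabridin vs melanosome, against 3 and 6 with an estimated correlation. With that correlation the lysosome list lost its call for melanosome vs control (adjusted p = 0.628) and the autophagy core its call for glabridin (0.0846). Fry, which tests a list's own direction and not its difference from other genes, gave adjusted p = 0.0183 both for the autophagy core, there turned to higher, and for nuclear oxidative phosphorylation in melanosome vs control, and 0.0208 for the lysosome list under glabridin. Without the genes that control lacked, nuclear oxidative phosphorylation passed at 0.0179, while the autophagy core (0.966), selective autophagy receptors (0.966) and melanosome uptake genes (0.948) turned sign without passing. Uptake genes did so with RLE factors too (0.944). Over left-out libraries, adjusted p ran from 0.0435 to 0.111 for nuclear oxidative phosphorylation with melanosomes, from 0.00841 to 0.935 for it with glabridin, and from 0.0223 to 0.67 for the lysosome list with glabridin. Uptake genes (0.849 to 0.96), heat shock (0.762 to 0.935) and matrix genes (0.508 to 0.815) also turned sign under glabridin without passing, the first without melanosome replicate 1 (0.907), the others without glabridin replicate 2 (0.935 and 0.693). The cause was not tested. Of the comparisons of a named gene with an alternative, 686 kept direction and side of the threshold, 9 gained a call (PMEL 3, MAP1LC3B 2, LAMP1 2 and TFEB 2) and 7 turned sign. All 7 concern TFEB, which did not pass in these 7. In melanosome vs control it was at 0.044 with RLE factors, 0.044 with DESeq2, 0.15 with limma on TPM, 0.14 with library totals and -0.050 to 0.020 over left-out libraries, and with glabridin at -0.17 to 0.0057 over left-out libraries.

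Replicate numbers did not pair the libraries, since same-numbered libraries correlated at -0.234 to 0.0503 in their deviations and not every library correlated best with its own number. With the replicate block, 8255, 5523 and 9507 genes were called in the 3 comparisons and 1574 with opposite signs, the covariance was -0.074, and nuclear oxidative phosphorylation passed for melanosome vs control (adjusted p = 0.0486). The block changed no other call of a list or named gene. With limma on log2(TPM + 1), log2 changes kept their sign but shrank for named genes with a group at a low level, as adding 1 before the log does. DMBT1 went from -3.43 to -2.17 with melanosomes and from -3.14 to -0.67 with glabridin, and NUPR1 from 4.61 to 3.29. Without control replicate 2, which held its only control counts, SOX10 went from 12.63 to 15.35. Depth limits the genes near 0 in control, whose folds are bounds only where all control libraries held 0 counts.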

Other observations

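Some targets of the aryl hydrocarbon receptor, which senses xenobiotics, fell with melanosomes and rose with glabridin. CYP1A1 went from 213 ± 0.927 CPM in control to 57.4 ± 1.08 CPM with melanosomes and 113 ± 8.70 CPM with glabridin, and TIPARP from 288 ± 1.89 to 164 ± 8.53 and 381 ± 35.7 CPM (SD, n = 3). The whole list of 19 tested genes did not pass with melanosomes (5 higher, 8 lower, also adjusted over the list alone; camera, adjusted p = 0.0791) or with glabridin (5 higher, 5 lower, 8 and 5 adjusted over the list alone; camera, adjusted p = 0.3). Among 22 inflammatory genes, 9 rose and 6 fell with melanosomes (camera, adjusted p = 0.626) and 5 rose and 4 fell with glabridin (camera, adjusted p = 0.432), both also adjusted over the list alone. IL1A, an epidermal alarmin gene, had log2 changes of 1.30 ± 0.20 and then 2.20 ± 0.19 SE, whereas CXCL1, a neutrophil chemokine gene, changed by -2.17 ± 0.25 SE with glabridin. Of 21 matrix genes, 6 rose and 4 fell with glabridin (7 and 4 adjusted over the list alone; camera, adjusted p = 0.783). With library totals alone, 3 matrix genes were higher and 5 lower with glabridin, 5 and 7 aryl hydrocarbon receptor targets, and 3 and 4 inflammatory genes.

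The remaining lists did not pass in either comparison (camera). Counts higher and lower with melanosomes, then with glabridin, were 16 and 5 (adjusted p = 0.305), then 15 and 3 (0.0933) of 34 mitochondrial biogenesis, dynamics and import genes, with PPARGC1A at 3.46 ± 0.15 SE with melanosomes. PPARGC1A rose in the libraries where melanocyte markers rose, and which cells its transcripts came from was not tested. The counts were 8 and 13 (0.944), then 9 and 7 (0.986) of 29 uptake and endosome traffic genes, and 6 and 12 (0.541), then 6 and 5 (0.601) of 23 basal keratinocyte genes. Heat shock proteins gave 3 and 5 (0.639), then 4 and 3 (0.793) of 12, and metallothioneins 4 and 0 (0.165), then 3 and 1 (0.593) of 5. Fibroblast markers gave 3 and 2 (0.255), then 1 and 2 (0.47) of 6, immune and endothelial markers 3 and 1 (0.859), then 1 and 3 (0.33) of 9, and histones 1 and 6 (0.165), then 2 and 5 (0.637) of 13. All these counts were the same adjusted over the list alone. With melanosomes, lists not passing were also selective autophagy receptors (5 and 7 of 19, 0.906), the unfolded protein response (6 and 4 of 19, 0.859), cholesterol synthesis (14 and 4 of 25, 0.217) and p53 targets (8 and 5 of 21, 0.741), again the same adjusted over the list alone. With library totals alone some of these balances turned or evened out, so they hold only relative to the TMM scale. Higher and lower with melanosomes were then 11 and 8 uptake genes, 6 and 3 heat shock genes, 7 and 2 selective autophagy receptors and 8 and 9 basal keratinocyte genes. With glabridin they were 5 and 11 uptake genes, 4 and 12 basal keratinocyte genes, 2 and 3 heat shock genes, 1 and 1 metallothioneins, and 10 and 9 genes of mitochondrial biogenesis, dynamics and import. Mean and test differed in sign with melanosomes for the autophagy core, selective receptors, uptake genes and immune markers, and with glabridin for histones and uptake genes. Median and test did so with melanosomes for aryl hydrocarbon receptor targets and the unfolded protein response, and with glabridin for keratinocyte differentiation and uptake genes.

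The tests in this part were chosen after the result was seen, except those of GC content and length at the 2-fold line, and of leaving out glabridin replicate 2. The splits of the 6 libraries of each comparison into 3 and 3 number 10 with the real split, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many genes. The real splits called 8691, 6111 and 9774 genes by edgeR and the highest of the other splits 0 each, with 63, 1629 and 311 genes at an unadjusted p under 0.05. Each other split mixes libraries of groups that differ in many genes, which widens the spread within its sets. Few calls were therefore likely from the outset, and the 0 does not show how many genes chance alone would give.

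The 234 transcripts that control lacked and both melanosome-laden groups held are a pattern that could come from RNA of pigment cells, carried with the melanosomes or from such cells in the culture, from the scaling, or from the keratinocytes themselves. Scaled library sizes differed by at most 1.30-fold, whereas the share of PMEL, which is not among the 234 and was named in advance, was at least 313-fold higher in each melanosome-laden library than in any control library, which argues against depth or scaling. Of the tested melanocyte markers, a list written before the data were seen, 95.5% were higher, 9 of the 22 were among the 234 genes and 7 were at 1 CPM or more in control, which is consistent with pigment-cell RNA but does not show whether pigment cells were in the culture. Of the abundant markers PMEL reached 2109 CPM and SOX10 117 CPM. Transcription by the keratinocytes cannot be told apart from pigment-cell RNA by these values, because reads do not name their cell. Basal keratinocyte genes went both ways, with 39.1% lower and 8 of 23 higher on library totals. This cannot decide between the 2, because their log2 changes spread widely (SD 0.67) and would hide a small dilution by other RNA.

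The 811 genes that were called and at least 2-fold lower with melanosomes, among them AKAP9 and TRIP11, had a median GC content of 0.424 against 0.488 for all tested genes. After each library's GC trend was removed, 96.9% were still called lower and their median log2 change went from -1.27 to -1.12 (SD 0.56). With the length trend removed, these values were 98.0% and -1.13 (SD 0.53). So neither trend, as fitted over all genes, accounts for these falls as the whole cause. The genes were chosen for large falls, so a bias that differs between genes of like GC content or length is not excluded. Between the bounds set beforehand, 58.5% and 65.4% stayed at least 2-fold lower, so a part played by GC content or length cannot be told apart from a response of the cells. Dilution by RNA of other cells as the whole cause would lower genes active only in keratinocytes alike. On library totals the 23 basal keratinocyte genes had a median log2 change of -0.11 (SD 0.67), above -1 by more than that SD. The other cells may hold RNA of these genes too, which was not tested. So this median cannot decide whether dilution was the whole cause or a part. A response of the keratinocytes to melanosomes stays open as a hypothesis.

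Under glabridin the transcripts that control lacked changed unequally. Carried RNA of 1 fixed mixture at another amount would keep their ratios, yet scaled to these 234 genes alone, 37 were higher and 35 lower with glabridin by edgeR (30.8%), which argues against it. PDK4 was higher by 2.07 ± 0.12 SE (adjusted p = 5.28e-09) and A2M by 1.34 ± 0.09 SE (adjusted p = 2.11e-08), while OCA2 was at -0.82 ± 0.09 SE (adjusted p = 1.26e-05) on that scale by edgeR. Without glabridin replicate 2, whose marker sum was the highest of its group, 29.9% were still called, so that library alone is argued against. RNA of unequal decay and cells that respond to glabridin may each give such a pattern, and which of these holds was not tested.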
